A study of Homo sapiens with 12 samples.

How the data were processed

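The deposited table held estimated counts per gene, with fractional values, for all 12 libraries and 58735 genes. Per the submitters' processing notes, STAR, RSEM and DESeq2 were used with the GRCh38 assembly. The notes assign no role or version to these tools and name no gene annotation. No normalisation is named for the deposited counts, and between 11.2% and 13.6% of a library's values, zeros included, were not whole numbers. Per the labels' protocols, cells were seeded in triplicate and cultured overnight, and poly-A RNA was made into libraries with a stranded kit. The strand setting used in counting is not given in the sources used here, so values of genes that overlap on opposite strands are uncertain. The same holds for paralogs that share reads. How the knockouts were made, and whether each knockout culture grew from a single cell, is not given in the sources used here.

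Gene identifiers were matched to GENCODE release 29, which held all 58735 of them, and 41937 genes took their symbol from a reference table. Of the genes, 26656 were at 0 in every library. Estimated counts were rounded to whole numbers. Genes were kept with the filterByExpr function of edgeR 4.0.16 by group, which left 17534 tested genes, and library sizes were scaled with trimmed mean of M-values (TMM) factors. One model with 4 groups of 3 libraries was fitted to all 12 libraries, with 8 residual degrees of freedom and no replicate block. Comparisons used the edgeR quasi-likelihood test with robust dispersion, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A gene rose, fell or changed where it passed that threshold. Changes are log2 ratios of the knockout label over wild type, given with the standard error (SE) of the fit. Levels are counts per 1000000 (CPM), given as mean ± SD over 3 libraries. A fold change against a group at 0 is a lower bound, computed against a floor of 3 counts over the group. With 1 to 3 counts in the lower group the ratio is given with a 95% counting interval. These intervals and floors cover counting error only. For each gene the spread was estimated over the 4 groups together, so the spread in 1 line bears on the p-values of the other. The p-values measure this pooled spread between the triplicate cultures. The labels do not say whether these came from one source culture, and they name no separately made knockouts, so the spread between such knockouts is not known.

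The 30 gene lists, the test, the alternatives and the rule for naming genes were set before the data were examined. Lists with at least 5 tested genes were compared with all other genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes. The test was two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. A list passed where its adjusted p was under 0.05. The lists covered the death receptor pathway, the BCL2 family, necroptosis and pyroptosis, NF-kB targets, the type I interferon response and MHC class I and class II presentation. For B cell state they covered B cell receptor signalling, immunoglobulin constant genes, germinal centre B cell, activated B cell and plasma cell genes. For growth and metabolism they covered mitosis and G2/M, DNA replication, MYC and ribosome biogenesis, cytosolic ribosomal proteins, p53 targets, the unfolded protein and integrated stress response, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation and mitochondrially encoded RNA. The remaining lists were immediate early and heat shock genes, immune recognition ligands, chemokines, cytokines and their receptors, adhesion and migration, markers of T and NK cells, of myeloid cells and of epithelial and stromal cells, and the neighbours of CFLAR on 2q33.

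Named genes followed this rule. CFLAR was named in every comparison. For each knockout comparison the 8 genes with the largest positive and the 8 with the largest negative log2 change were named, among those past the threshold, with at least 5 CPM in the higher group and no overlap between wild-type and knockout libraries. Non-coding, pseudogene and clone-type names, antigen receptor segments and Y-linked genes were left out there. Up to 4 members of each list with the smallest adjusted p were eligible, or the 2 with the highest level where none passed. Genes changed the same way in both lines added 6 up and 6 down, and the difference between the lines added the 5 most positive and 5 most negative. Germinal centre, activated B cell, BCL2 family and death receptor members with the smallest adjusted p served the comparison of the wild-type lines. Genes beside CFLAR and genes at the edges of shifted stretches were named for their position, after their values were seen.

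A scan for chromosome stretches whose genes shifted together was added after the data were seen. Genes with at least 2 CPM were ordered along each chromosome and their log2 changes were limited to 1.5 in size. Stretches of at least 15 genes were divided where the change in mean exceeded the 95th percentile of 200 shuffles of gene order. A stretch counted as shifted where its median was at least 0.15 in size. A gene was called switched where one group of a line had at most 3 counts in total and the other a mean of at least 1 CPM.

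Alternatives were the DESeq2 1.42.0 Wald test, DESeq2 size factors in edgeR, library size without TMM, no filter on low counts, a filter of 1 CPM in 3 libraries, the compared libraries only and a block for the replicate number. Others left out abundant genes (mitochondrially encoded, immunoglobulin and the 20 most abundant), each library in turn, or, added after the data were seen, the genes on shifted stretches. Lists were also tested with an estimated correlation and with fry. Simulated counts with known changes tested the scripts. In TMD8, 90% of 1.5-fold and 98% of 2-fold changes were recovered, with 18 unchanged genes called among 17059 tested. In SU-DHL-4 the shares were 92% and 100%, with 8 unchanged genes called. Changes present in one line were recovered by the test of the difference at 73% to 80% for 1.5-fold and 89% to 91% for 2-fold. A list shifted by 0.3 was recovered with 1 other list called, and the scan recovered 59 of 59 genes of a simulated stretch and 1 gene outside it. Simulated genes varied independently, so the list check did not test the effect of correlation between genes. The simulated stretch was shifted about as far as the long arm of chromosome 2 after CFLAR in SU-DHL-4. Recovery of smaller shifts, such as those found in TMD8, was not tested. Splicing, sequence variants and small insertions or deletions were not analysed here, since gene-level counts hold no such information. The software was R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.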

Results

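RNA was measured by poly-A sequencing in TMD8 and SU-DHL-4, established human lines of diffuse large B cell lymphoma. TMD8 is usually classed as activated B cell-like and SU-DHL-4 as germinal centre B cell-like. Each line had 3 libraries labelled CFLAR wild type and 3 labelled CFLAR knockout, all untreated, for 12 libraries in 4 groups. CFLAR encodes cFLIP, a caspase-8 relative that restrains caspase-8 activation at death receptors, and the labels present the series as a test of how far lymphoma cells depend on it. The comparisons ask how the baseline transcriptome of each line differs between the labels, and whether the difference is alike in both lines. Total estimated counts per library ran from 42856376 to 45333884 in TMD8 wild type and 41529681 to 50047549 under the TMD8 knockout label. They ran from 44707664 to 56746423 in SU-DHL-4 wild type and 52256858 to 58989586 in SU-DHL-4 knockout. Protein-coding genes held 96.3% to 97.5% of the counts of a library, and the 20 most abundant genes held 10.0% to 11.6%. The first principal component, which parted the lines, held 89.9% of the variance, and the next held 3.7%. The biological coefficient of variation was 0.078.

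CFLAR itself (ENSG00000003402, GRCh38 chromosome 2, 201116104 to 201176687, plus strand) went against the label in TMD8. In TMD8 it was at 337 ± 20.4 CPM (SD, n = 3) in wild type and 458 ± 23.2 CPM (SD, n = 3) under the knockout label, a rise of 0.44 (SE 0.06, 1.36-fold, edgeR adjusted p = 0.000135). The wild-type libraries stood at 345.2, 352.1 and 313.8 CPM and those labelled knockout at 431.6, 474.9 and 467.8 CPM. In SU-DHL-4 it fell from 10.6 ± 0.956 to 4.94 ± 0.383 CPM (SD, n = 3), a change of −1.10 (SE 0.09, 0.47-fold, adjusted p = 3.99e-08). The SU-DHL-4 wild-type libraries held 9.7, 10.4 and 11.6 CPM and the knockout libraries 4.7, 4.8 and 5.4 CPM. The change differed between the lines by −1.55 (SE 0.11, adjusted p = 2e-08). Between the wild types, CFLAR RNA was 31.8-fold lower in SU-DHL-4 than in TMD8 (−4.99, SE 0.08, adjusted p = 7.51e-18). Gene-level counts do not show a small insertion or deletion that ends the protein, so the TMD8 libraries are called labelled knockout throughout.

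**Figure D1:**
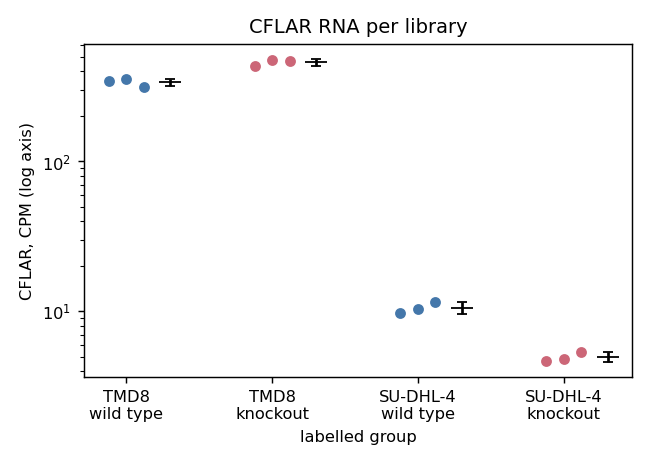
CFLAR level in CPM (log axis) in each of the 12 libraries, grouped by line and label, with points for libraries and bars for the mean and SD of each group. The TMD8 libraries labelled knockout stand at 431.6 to 474.9 CPM, above all 3 TMD8 wild-type libraries, and the SU-DHL-4 knockout libraries stand at 4.7 to 5.4 CPM, below all 3 of their wild type.

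In SU-DHL-4 the neighbours of CFLAR on chromosome 2 were lower as well. HYCC2 (−0.59), NDUFB3 (−0.73), CASP8 (−0.61), TRAK2 (−0.77) and TMEM237 (−0.92) all fell, while ORC2, the next gene towards the centromere, was at −0.05 (adjusted p = 0.523). Beyond ORC2 the change was smaller and mixed, with NIF3L1 (−0.37), PPIL3 (−0.26) and KCTD18 (−0.24) lower and SGO2 (0.25) and CLK1 (0.22) higher, and the 9 genes in the 1 Mb before CFLAR had a median of −0.24 with 5 lower and 2 higher. CASP8 encodes the caspase that cFLIP restrains, and it fell from 19.6 ± 0.484 to 12.8 ± 0.581 CPM. From the far side of CFLAR to the end of the long arm, 142 genes had a median change of −1.0 (quartiles −1.18 and −0.73). Of these, 131 fell and 5 rose. The 584 genes before CFLAR had a median of 0.01. In TMD8 the 164 genes after CFLAR also had a median of 0.01. The fixed list of CFLAR neighbours fell in SU-DHL-4, with 9 members lower and 3 higher of 16 (the same 9 and 3 adjusted over the list alone, camera adjusted p = 0.00483). That call was lost with an estimated correlation (adjusted p = 0.337) and without the genes on shifted stretches (adjusted p = 0.387). In TMD8 the list had 3 lower and none higher of 16 (adjusted p = 0.577). A scan along the chromosomes placed the start of the lowered stretch at HYCC2, where 145 genes up to the telomere had a median of −0.992, a 0.5-fold level.

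**Figure D2:**
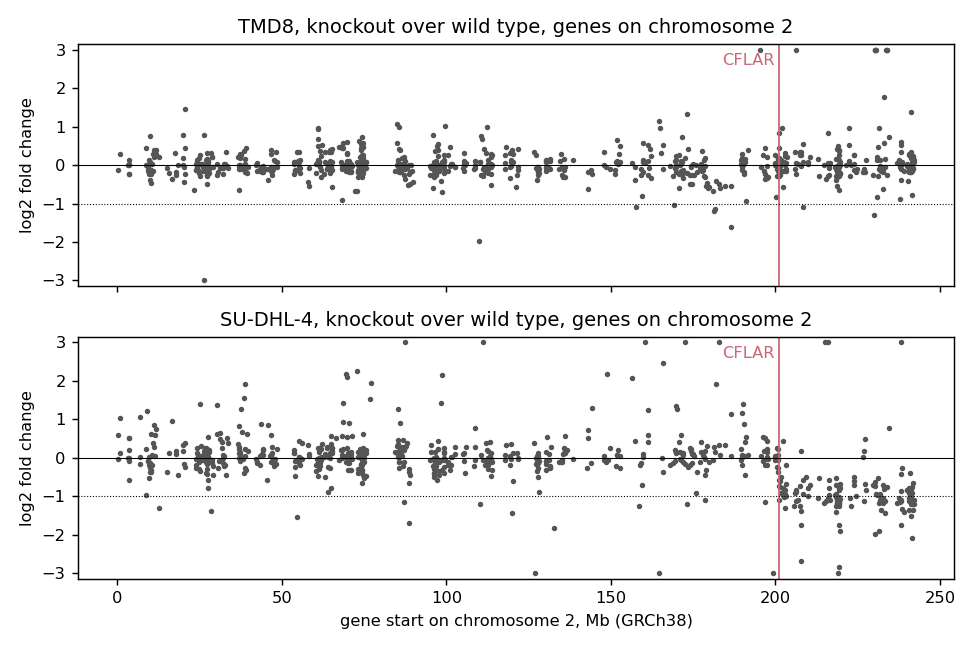
Log2 change of knockout label over wild type (vertical axis) for genes along chromosome 2 (horizontal axis, megabases on GRCh38) in TMD8 and SU-DHL-4, with one point per gene, points beyond 3 in size drawn at 3, and CFLAR marked. In SU-DHL-4 the level steps down near CFLAR, from HYCC2 on, and the genes after CFLAR have a median of −1.0 up to the telomere, and in TMD8 the genes on that side have a median of 0.01.

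In TMD8, interferon-stimulated genes fell under the knockout label. These genes are induced by type I interferon and restrain viruses. OAS2 fell from 126 ± 2.69 to 38.6 ± 1.91 CPM (−1.70, SE 0.06) and IFIT1 from 23.8 ± 1.39 to 3.52 ± 1.01 CPM (−2.75, SE 0.19). IFITM1 fell too (−2.44, SE 0.11). In the list of interferon genes 34 of 43 fell and 2 rose (37 and 2 adjusted over the list alone), with a median of −1.15 (camera adjusted p = 2.58e-16, and 0.00179 with an estimated correlation). The 2 that rose were SP110 and CXCL10. NF-kB targets moved the other way, and these include cytokines and feedback regulators of the pathway on which many activated B cell-like lines depend. LTB, the cytokine lymphotoxin beta, rose from 1.02 ± 0.174 to 9.88 ± 1.47 CPM (3.27, SE 0.15), NFKBIZ from 90.5 ± 5.89 to 181 ± 6.5 CPM (1.00, SE 0.06), TRAF1 by 1.21 (SE 0.09) and NFKB2 by 0.77 (SE 0.06). In that list 32 of 47 rose and 2 fell (35 and 3 adjusted over the list alone), with a median of 0.55 (adjusted p = 9.31e-12, but 0.106 with an estimated correlation).

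Cholesterol synthesis enzymes also rose in the TMD8 libraries labelled knockout, and mitotic genes fell. INSIG1, which holds the sterol sensor in the endoplasmic reticulum, rose from 140 ± 9.56 to 266 ± 22.4 CPM (0.92, SE 0.06). HMGCS1 rose by 0.59 (SE 0.06), ACAT2 by 0.64 and CYP51A1 by 0.55. Of 24 genes in the list 19 rose and none fell (20 and 1 adjusted over the list alone), with a median of 0.40 (adjusted p = 1.18e-09, but 0.14 with an estimated correlation). Of the 19, 3 lay on shifted stretches, INSIG1 and CYP51A1 among them on a raised stretch of 7q with a median of 0.225. FOXM1, a transcription factor of mitotic genes, fell (−0.55), as did the kinases AURKA (−0.53) and PLK1 (−0.47), and MKI67 (−0.42, SE 0.06). Of 33 mitotic genes 26 fell and none rose (30 and none adjusted over the list alone), with a median of −0.25 (adjusted p = 6.37e-12, but 0.183 with an estimated correlation). The mitochondrially encoded share of counts was 5.32 ± 0.455% in wild type and 5.85 ± 0.504% under the knockout label. Mitochondrially encoded RNA as a list had 1 lower and none higher of 13 (adjusted p = 0.911).

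Around the death receptors, where cFLIP acts, TMD8 genes moved both ways. RIPK1, the kinase recruited by TNF receptor 1, fell (−0.51, SE 0.08) and so did BID, the substrate of caspase-8 (−0.29). TNF rose by 2.29 (SE 0.35), from 23.1 ± 1.3 to 113 ± 55.5 CPM, with 51.4, 160 and 128 CPM in the libraries labelled knockout, and the ligase BIRC3 by 0.35 (SE 0.08). The list had 5 higher and 4 lower of 26 (adjusted p = 0.747). In the BCL2 family the pro-apoptotic PMAIP1 rose by 1.20 (SE 0.09) and the protective BCL2L1 by 0.61 (SE 0.05), while the pro-apoptotic BIK (−1.33) and BMF (−0.45) fell, with 4 higher and 5 lower of 18 (adjusted p = 0.813). Necroptosis and pyroptosis genes had 1 higher and 3 lower of 14 (adjusted p = 0.308).

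B cell state genes in TMD8 were mixed as well. BCL6, the repressor that defines germinal centre B cells, rose from 42.5 ± 1.84 to 88.1 ± 3.49 CPM (1.05, SE 0.05), while SERPINA9, another germinal centre gene, fell (−2.16, SE 0.12). The germinal centre list had 7 higher and 8 lower of 28 (adjusted p = 0.375) and the activated B cell list 12 higher and 9 lower of 29 (adjusted p = 0.577). INPP5D, the SHIP1 phosphatase that dampens B cell receptor signals, rose by 1.76 (SE 0.07), with 7 higher and 11 lower of 31 in the receptor list (adjusted p = 0.352). JCHAIN rose by 1.70 and IGHD fell (−2.15), with 3 higher and 4 lower of 14 immunoglobulin constant genes (adjusted p = 0.911) and 9 higher and 2 lower of 16 plasma cell genes (adjusted p = 0.112). In antigen presentation HLA-B fell (−0.33, SE 0.05). MHC class I genes had 1 higher and 9 lower of 21 (adjusted p = 0.0515) and class II genes 1 higher and 2 lower of 18 (adjusted p = 0.966).

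The chemokines CXCL10 (1.89, SE 0.17) and CXCL13 (1.67) rose in TMD8, in a list with 15 higher and 6 lower of 38 (adjusted p = 0.0515). The integrin ITGA4 fell (−1.19, SE 0.07) and the lectin LGALS1 rose by 1.02, in an adhesion list with 9 higher and 6 lower of 26 (adjusted p = 0.919). Immune recognition ligands had 10 higher and 2 lower of 27 (adjusted p = 0.375). Oxidative phosphorylation had 2 higher and 10 lower of 40 (adjusted p = 0.0515), DNA replication 2 and 9 of 36 (adjusted p = 0.184), MYC and ribosome biogenesis 1 and 2 of 29 (adjusted p = 0.261) and ribosomal proteins 3 and 1 of 38 (adjusted p = 0.919). Stress lists did not pass either, with 3 higher and 3 lower of 27 p53 targets (adjusted p = 0.569), 8 and 6 of 30 stress response genes (adjusted p = 0.577), 4 and 4 of 22 immediate early and heat shock genes (adjusted p = 0.627) and 1 and 5 of 30 glycolysis and hypoxia genes (adjusted p = 0.561). Among markers of other cell types, none of 10 tested T and NK cell genes changed (adjusted p = 0.919), 1 rose and 2 fell of 9 myeloid genes (adjusted p = 0.261) and 4 rose and 1 fell of 8 epithelial and stromal genes (adjusted p = 0.443).

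Some TMD8 genes went from no or nearly no RNA to clear expression. SP140, a nuclear body protein of lymphocytes, had 0 counts in the wild-type libraries and stood at 84.3 ± 6.23 CPM under the knockout label, at least 3750-fold higher. Its neighbours on 2q37 shared this. SP140L was at least 486-fold higher, SP110 had a ratio of 2190 (95% counting interval 748 to 10600) and USP40 one of 1100 (196 to 43400). ZDBF2, also on chromosome 2, was at least 1200-fold higher, and TBC1D14 on chromosome 4 had a ratio of 2920 (809 to 24100). In the other direction L1TD1 fell from 14.5 ± 1.3 to 0.0782 ± 0.0327 CPM (−7.48, SE 0.24), SELENOW from 17.2 ± 0.655 to 0.185 ± 0.108 CPM (−6.52, SE 0.19), and PNMA2 (−6.02) and NXN (−5.10) fell as well. In all, 10 genes were switched on and 8 switched off in TMD8, counting at most 3 counts in one group and at least 1 CPM in the other.

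Across 17534 tested genes, 2138 rose and 2075 fell in TMD8, 24% of those tested, and 363 and 324 of them changed at least 2-fold. The counts were 1376 and 1348 without TMD8 wild-type replicate 2, and 1285 and 1088 when the 6 TMD8 libraries were fitted alone. Of the 10 ways to split these libraries into 3 and 3, all gave at least as many passing lists as the real one, which had 4, so that number did not stand out from other splits. For TMD8 lists that did not pass, the counts adjusted over the list alone differed from those above by at most 3.

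In SU-DHL-4, MHC class I genes rose in the knockout. They present peptides to CD8 T cells. HLA-B rose from 29.6 ± 0.674 to 62.7 ± 1.59 CPM (1.08, SE 0.06), HLA-E by 0.75 and the peptide-trimming ERAP1 by 0.80. Of 21 genes in the list 16 rose and 1 fell (17 and 2 adjusted over the list alone), with a median of 0.41 (adjusted p = 1.3e-06, but 0.145 with an estimated correlation). Interferon-stimulated genes rose as a list although not as one block. EPSTI1 rose by 1.44 and DTX3L by 1.24 (SE 0.09), while OAS2 fell (−1.70, SE 0.07) and so did ISG20 on a lowered stretch of chromosome 15 (−1.18). The list had 20 higher and 5 lower of 43 (21 and 6 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 0.00182, but 0.184 with an estimated correlation). Among the 20 members with at least 1 CPM in a group of SU-DHL-4, 10 rose and 3 fell, with a median of 0.31. Cholesterol synthesis fell, led by HMGCS1 (−0.89, SE 0.06), INSIG1 (−0.66), FDFT1 (−0.62) and SQLE (−0.57). That list had 17 lower and 2 higher of 24 (18 and 2 adjusted over the list alone), with a median of −0.38 (adjusted p = 2.19e-05, but 0.337 with an estimated correlation).

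Growth-related lists shifted by smaller amounts in SU-DHL-4. NDC80, part of the kinetochore, rose by 0.69 (SE 0.05), PLK1 by 0.55 (SE 0.06), HMMR by 0.57 and CDC20 by 0.55. NDC80 lay on a raised stretch of 18p, whose median was 0.699. Of 33 mitotic genes 16 rose and 2 fell (17 and 2 adjusted over the list alone), with a median of 0.16 (adjusted p = 0.00343, but 0.587 with an estimated correlation). Among them, 1 that rose and 2 that fell lay on shifted stretches. DNA replication genes fell, with 14 lower and 2 higher of 36 (15 and 2 adjusted over the list alone), a median of −0.16 and POLD1 at −0.44 (adjusted p = 0.00449, but 0.758 with an estimated correlation). Ribosomal protein genes had 19 lower and none higher of 38 (the same adjusted over the list alone), with a median of −0.15 (adjusted p = 2.56e-05, but 0.65 with an estimated correlation). The steepest of them lay on lowered stretches, RPL35 (−1.06) and RPL12 (−0.72) on 9q and RPL4 (−0.75) and RPLP1 (−0.78) on 15q. MYC and ribosome biogenesis genes had 8 lower and none higher of 29 (the same adjusted over the list alone), a median of −0.11 and the nucleolar NCL, on the lowered stretch of 2q, at −1.19 (adjusted p = 0.0275, but 0.823 with an estimated correlation and 0.0616 without SU-DHL-4 wild-type replicate 2). Mitochondrially encoded RNA rose, with MT-CO2 at 0.45 (SE 0.06) and MT-CYB at 0.41, 10 higher and none lower of 13 (12 and none adjusted over the list alone) and a median of 0.33 (adjusted p = 0.0015, but 0.561 with an estimated correlation). The mitochondrially encoded share of counts was 4.38 ± 0.168% in wild type and 5.54 ± 0.17% in the knockout and that share was read here as a sign of cell and RNA quality.

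Death receptor genes in SU-DHL-4 included higher TRAIL receptors, with TNFRSF10B at 0.54 (SE 0.07) and the decoy TNFRSF10D at 1.01 (SE 0.13), beside the lower CASP8. The list had 10 higher and 3 lower of 26 (adjusted p = 0.253). BIK rose by 2.05 (SE 0.14) and PMAIP1 by 0.77, HRK (−2.13, SE 0.24) and BCL2L1 (−0.41) fell, with 5 higher and 4 lower of 18 in the BCL2 family (adjusted p = 0.778). PYCARD, the inflammasome adaptor, rose by 3.38 (SE 0.20), GSDMD fell (−1.89) and RIPK3, with 0 counts in the knockout, was at least 6.83-fold lower, in a list with 4 higher and 3 lower of 14 (adjusted p = 0.721). NF-kB targets had 13 higher and 5 lower of 47 (adjusted p = 0.144), and they included TRAF1 (1.16) and CD83 (−1.34). Of the 5 that fell, 3 lay on shifted stretches, against 0 of the 13 that rose. The NF-kB list passed without the genes on shifted stretches, and by fry it was higher (adjusted p = 0.0444). With an estimated correlation in camera it did not pass (adjusted p = 0.72). Among immune recognition ligands CD70 fell (−2.85, SE 0.11) and CD86 rose by 1.16 (SE 0.06), with 9 higher and 5 lower of 27 (adjusted p = 0.117). MHC class II genes had 9 higher and 1 lower of 18 (adjusted p = 0.0544).

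Surface and differentiation genes shifted singly in SU-DHL-4. IL21R rose by 1.77 (SE 0.06), in a chemokine and cytokine list with 11 higher and 5 lower of 38 (adjusted p = 0.0676). ITGB2 rose by 1.69 (SE 0.07), while CD24 (−2.64, SE 0.09) and ANXA5 (−2.13, SE 0.06) fell, in an adhesion list with 9 higher and 3 lower of 26 (adjusted p = 0.097). BACH2, a repressor of plasma cell fate, fell (−1.65, SE 0.09) and LMO2 rose by 3.10 (SE 0.25), with 6 higher and 6 lower of 28 germinal centre genes (adjusted p = 0.778). SH3BP5 rose by 1.82 and CCND2 fell (−2.23), with 10 higher and 9 lower of 29 activated B cell genes (adjusted p = 0.721). Plasma cell genes had 6 higher and 3 lower of 16 (adjusted p = 0.356), B cell receptor genes 8 and 9 of 31 (adjusted p = 0.778) and immunoglobulin constant genes none and 4 of 14 (adjusted p = 0.264). CDKN1A, the p53-induced cell cycle inhibitor, fell (−2.52, SE 0.20), with 6 higher and 6 lower of 27 p53 targets (adjusted p = 0.778). The chaperone HSP90B1 rose by 0.88 (SE 0.05), with 11 higher and 4 lower of 30 stress response genes (adjusted p = 0.148). Glycolysis and hypoxia had 4 higher and 1 lower of 30 (adjusted p = 0.778), oxidative phosphorylation 5 and 6 of 40 (adjusted p = 0.778) and immediate early and heat shock genes 4 and 5 of 22 (adjusted p = 0.662). Markers of T and NK cells had 2 higher and 3 lower of 10 (adjusted p = 0.498), myeloid markers 1 and 1 of 9 (adjusted p = 0.778) and epithelial and stromal markers 1 and 1 of 8 (adjusted p = 0.87).

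The steepest changes of SU-DHL-4 were again from near 0. APP, the amyloid precursor, had a ratio of 643 (95% counting interval 178 to 5320) and TMEM178B one of 457 (126 to 3780). ZC3HAV1, an antiviral RNA-binding protein, rose from 0.36 ± 0.103 to 57.3 ± 3.35 CPM (7.28, SE 0.18), and IGSF11, GPX7, MREG, TECPR1 and MPP1 rose by 6.84 to 8.29. ZNF711, an X-linked zinc finger gene, was at least 729-fold lower with 0 counts in the knockout. CPT1A, which brings fatty acids into mitochondria, fell from 39.8 ± 1.58 to 0.0634 ± 0.0604 CPM (−9.19, SE 0.27), and APOBEC3C from 47 ± 0.947 to 0.853 ± 0.0695 CPM (−5.78, SE 0.13). TFCP2, COBLL1, APOBEC3G and BIN1 fell, with changes of −5.59 to −4.63. By the count used for TMD8, 12 genes were switched on and 12 off, none of them the same way in TMD8.

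**Figure D3:**
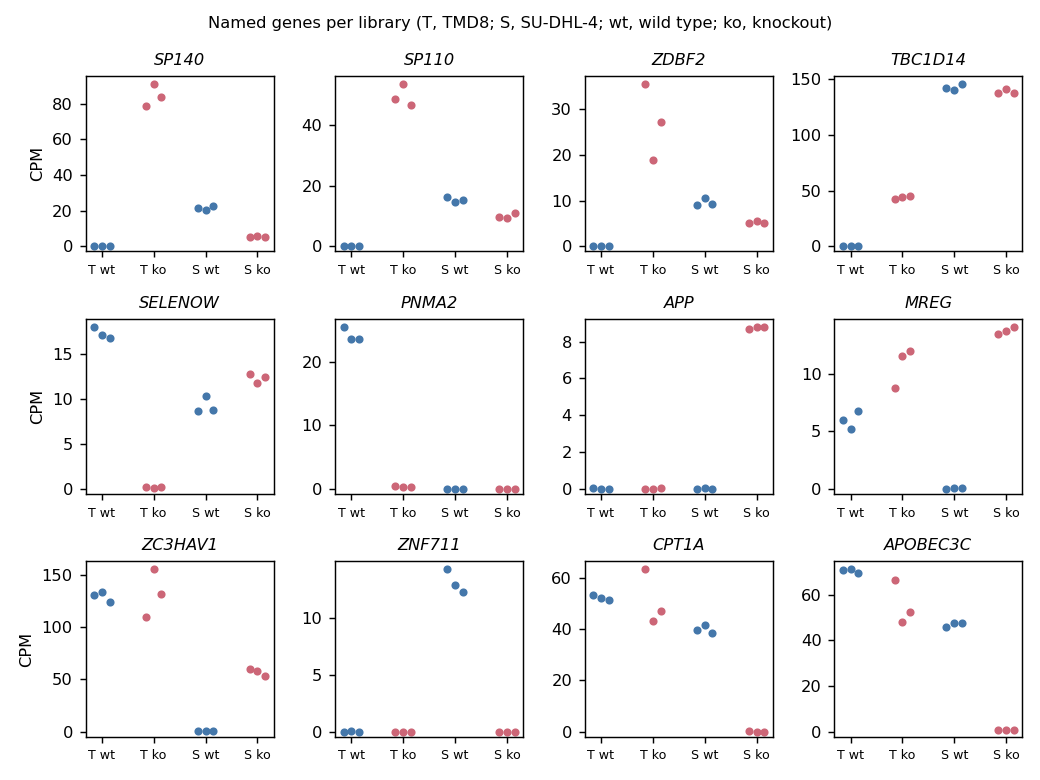
Level in CPM (vertical axis) of 12 named genes in each library, one panel per gene and one point per library, for TMD8 (T) and SU-DHL-4 (S) wild type (wt) and knockout label (ko). SP140, SP110, ZDBF2 and TBC1D14 are at or near 0 in the TMD8 wild type, SELENOW and PNMA2 under the TMD8 knockout label, APP, MREG and ZC3HAV1 in the SU-DHL-4 wild type, and ZNF711, CPT1A and APOBEC3C at or under 0.853 ± 0.0695 CPM in the SU-DHL-4 knockout.

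Across the tested genes 3012 rose and 2962 fell in SU-DHL-4, 34.1% of those tested, and 841 and 679 of them changed at least 2-fold. Of the genes that fell, 496 (16.7%) lay on chromosome stretches that shifted together, against 115 (3.8%) of those that rose. Of the 10 ways to split the 6 libraries into 3 and 3, only the real one gave as many as its 9 passing lists, and the next gave 7. None of the 9 calls held with an estimated correlation. For SU-DHL-4 lists that did not pass, the counts adjusted over the list alone differed by at most 4.

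**Figure D4:**
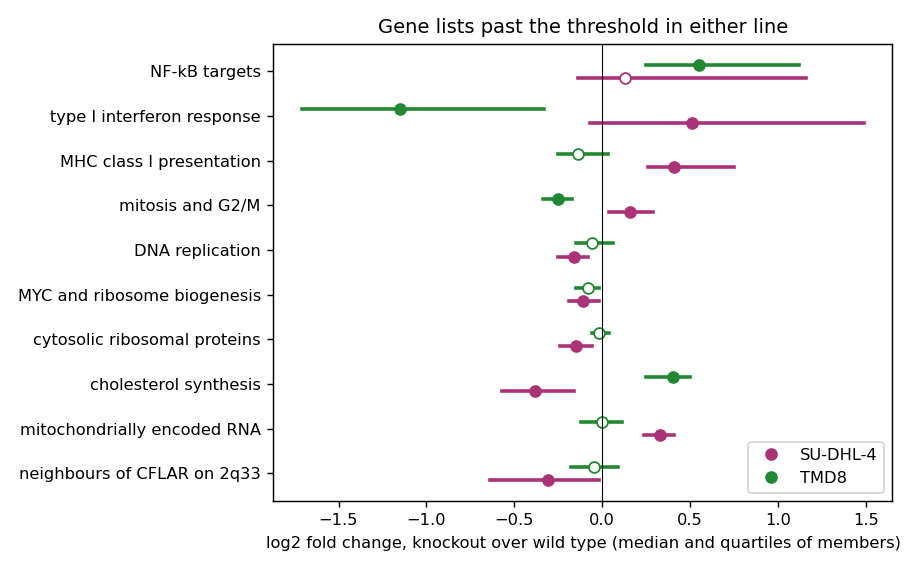
Median log2 change of each gene list (horizontal axis) in TMD8 and SU-DHL-4 by list (vertical axis), with lines for the quartiles of the members, filled points for lists past adjusted p 0.05 by camera and open points for the others. Interferon genes have medians of −1.15 in TMD8 and 0.51 in SU-DHL-4, cholesterol synthesis 0.40 and −0.38, and mitosis −0.25 and 0.16.

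By the labels as given, interferon, sterol and mitotic genes changed in opposite directions in the lines, and the test of the difference (SU-DHL-4 minus TMD8) was past the threshold for each. ISG15, a ubiquitin-like protein induced by interferon, differed by 1.89 (SE 0.12) and EPSTI1 by 2.93. The interferon list had 31 positive and 2 negative differences of 43 (32 and 4 adjusted over the list alone), with a median of 1.55 (camera adjusted p = 5.77e-11, and 0.00719 with an estimated correlation). Among its 19 members with at least 1 CPM in both lines, 16 differences were positive and 2 negative, with a median of 0.94. INSIG1 differed by −1.58 (SE 0.09, adjusted p = 2.55e-09) and HMGCS1 by −1.48 (SE 0.09), in a cholesterol list with 18 negative and no positive differences of 24 (the same adjusted over the list alone, adjusted p = 1.76e-09, but 0.175 with an estimated correlation). NDC80, on the raised SU-DHL-4 stretch of 18p, differed by 0.98 (SE 0.07) and PLK1 by 1.01 (SE 0.09). The mitotic list had 26 positive and no negative differences of 33 (28 and none adjusted over the list alone, adjusted p = 2.21e-09, but 0.381 with an estimated correlation). MHC class I genes, among them HLA-B (1.41, SE 0.08), had 16 positive and 1 negative of 21 (the same adjusted over the list alone, adjusted p = 4.01e-07, but 0.0751 with an estimated correlation).

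NF-kB targets also differed as a list, with a median of −0.59, and there LTB differed by −3.21 (SE 0.20) and CD70 by −2.96. The list had 16 negative and 7 positive of 47 (18 and 7 adjusted over the list alone, adjusted p = 0.00792, but 0.754 with an estimated correlation). Ribosomal protein genes had 14 negative and no positive differences of 38 (15 and 1 adjusted over the list alone, adjusted p = 0.00157, but 0.898 with an estimated correlation). Mitochondrially encoded RNA had 7 positive and no negative of 13 (9 and none adjusted over the list alone, adjusted p = 0.0107, but 0.829 with an estimated correlation). In the cell death lists, BIK differed by 3.38 (SE 0.23, adjusted p = 1.6e-08), BCL2L1 by −1.02 (SE 0.08, adjusted p = 6.43e-08), TNFRSF10B by 0.69 (SE 0.10) and CASP8 by −0.59 (SE 0.08). Neither the death receptor list (8 positive and 2 negative of 26, adjusted p = 0.472) nor the BCL2 family (6 and 5 of 18, adjusted p = 0.966) passed. INPP5D, higher in TMD8 under the knockout label and lower in SU-DHL-4, differed by −2.57 (SE 0.10). In all, 2677 genes had a positive and 2600 a negative difference, 30.1% of those tested, and 863 and 814 of them differed at least 2-fold. The direction of each comparison between the lines rests on the TMD8 labels, which CFLAR RNA goes against. With exchanged labels CFLAR would stand at 0.74-fold in TMD8, so its RNA would not be lost under either labelling. CFLAR RNA therefore does not decide whether the labels were exchanged. Exchanged TMD8 labels would turn every TMD8 sign, so the medians of the interferon, cholesterol and mitotic lists there would be 1.15, −0.40 and 0.25, the same signs as in SU-DHL-4. The adjusted p of the difference would then be 0.00596 (0.232 with an estimated correlation), 0.822 and 0.144, and 5196 genes would differ. Other lists would then diverge, among them NF-kB targets (−0.55 in TMD8, 0.13 in SU-DHL-4, adjusted p = 1.02e-06, but 0.232 with an estimated correlation) and chemokines, cytokines and their receptors (adjusted p = 0.00539, but 0.126). In all, 9 lists would differ in place of 7, or none in place of 1 with an estimated correlation. Of 100 splits of the libraries within the lines 35 gave at least as many passing lists as the real one, which had 7.

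Genes that moved alike in the lines by the labels as given exceeded the number under independence by little. TRAF1, an adaptor of TNF receptors, rose by 1.21 in TMD8 and 1.16 in SU-DHL-4, and PFKFB2, LRRC32, FAM241A and CTXN1 rose in both by 0.86 or more. TNF rose in both by the threshold, but its SU-DHL-4 call (1.51, SE 0.48, adjusted p = 0.0398) was lost without any 1 of the 6 SU-DHL-4 libraries (adjusted p 0.0703 to 0.102). OAS2 fell in each (−1.70), and the heat shock protein HSPB1 fell in TMD8 (−1.46, SE 0.08) and in SU-DHL-4 (−2.97, SE 0.13). HDAC9, NEDD9, MYOM2 and EPS8L2 also fell in both. Genes higher in both lines numbered 481, where independence gives 367.3, and genes lower in both 417, where it gives 350.5. Opposite changes were as frequent, with 441 higher in TMD8 and lower in SU-DHL-4 (361.2 under independence) and 509 the reverse (356.4). With the TMD8 labels exchanged, these 950 would be the genes that moved alike and the other 898 the opposite ones. Without TMD8 wild-type replicate 2 the number lower in both was 257 and the number higher in TMD8 and lower in SU-DHL-4 was 270. Among genes with at least 1 CPM in both lines, 419 were higher in both (345.9 under independence) and 371 lower in both (369.2). Of these genes, 402 were higher in TMD8 and lower in SU-DHL-4 (362.2) and 451 the reverse (352.6). Across genes, which are not independent replicates, the changes had a Pearson correlation of −0.01 and a Spearman correlation of −0.003. Genes with at least 1 CPM in both lines that rose or fell in one were also tested as lists in the other by camera in limma, and each of the 4 tests gave an adjusted p = 0.807 (0.372 to 0.807 before adjustment).

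The wild-type lines were compared to place their starting levels, and they stand for these lines only. Germinal centre genes were higher in SU-DHL-4. MME, which encodes CD10, was at least 10400-fold higher with 0 counts in TMD8, and CD38 (7.19, SE 0.09), STAP1 (6.72, SE 0.11) and BCL6 (3.46, SE 0.05) were higher too. The list had 23 higher and 4 lower of 28 (adjusted p = 2.65e-05, and 0.0123 with an estimated correlation). Activated B cell genes were lower in SU-DHL-4, with IRF4 at −13.03, CCND2 at −5.75, SH3BP5 at −5.54 and PTPN1 at −4.02, and 26 lower and 2 higher of 29 (adjusted p = 1.87e-08, and 0.0118 with an estimated correlation). Interferon genes had 38 lower and 4 higher of 43 (adjusted p = 6.12e-08, and 0.0118 with an estimated correlation). NF-kB targets had 37 lower and 6 higher of 47 (adjusted p = 2.65e-05, but 0.182 with an estimated correlation). In the death receptor pathway TNFRSF1B was higher in TMD8 by a ratio of 17000 (95% counting interval 3050 to 672000), BIRC3 (−3.04, SE 0.09) was lower in SU-DHL-4 and TNFRSF10A was higher there (2.56, SE 0.07), with 8 higher and 18 lower of 26 (adjusted p = 0.0804). BCL2A1 was lower in SU-DHL-4 (−5.64, SE 0.11), and BID, BMF and BCL2L12 were lower there (−1.81 to −1.09), with 5 higher and 11 lower of 18 in the BCL2 family (adjusted p = 0.226). Counts in these lists adjusted over the list alone differed by at most 1. Of all tested genes 6589 were higher in SU-DHL-4 and 7382 lower, 79.7%, and 3442 and 4657 of them by at least 2-fold.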

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

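The tests against a response shared by both lines on 2q, of neighbouring switched genes, of exchanged TMD8 labels, of 1 divergent library, of the shifted stretches, and of the splits within TMD8, within SU-DHL-4 and between the wild-type lines were chosen after the results were seen, as were the scan for stretches and the count of switched genes between the wild-type lines. Leaving out each library in turn was set before the data were seen, and only its use on the 3 lists was chosen later. The results in this part differed between the lines by the test of the difference itself.

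CFLAR changed in opposite directions in the lines (0.44 in TMD8 and −1.10 in SU-DHL-4, adjusted p of the difference 2e-08), so the RNA level does not by itself identify a knockout in TMD8. In SU-DHL-4 the genes from CFLAR to the end of 2q fell together, and fewer copies of this stretch in the knockout culture are a candidate explanation. If copies were fewer, genes of every level would fall alike, and genes of low, middle and high wild-type level had medians of −0.81, −1.08 and −0.98. The 675 genes elsewhere matched on GC content, exon length and level had a median of 0, which argues against these properties. The same genes had a median of 0 in TMD8 as well, which argues against a response shared by the libraries labelled knockout. No DNA was measured and these tests used RNA only, so a loss of copies, and what lowered CFLAR RNA, stay open.

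GPX7 (adjusted p of the difference 7.3e-12), TECPR1 (4.51e-11), MPP1 (4.9e-12) and ZC3HAV1 (8.59e-12) were near 0 in the SU-DHL-4 wild type and not in its knockout, with no such step in TMD8. SELENOW (4.52e-12) was near 0 in the TMD8 libraries labelled knockout, and SP140 (8.68e-15), ZDBF2 (5.06e-08), SP140L (8.36e-12), SP110 (4.8e-14) and TBC1D14 (3.03e-15) were at or near 0 in the TMD8 wild type.

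Genes at or near 0 in one group and expressed in the other numbered 18 in TMD8 and 24 in SU-DHL-4, against 943 between the wild-type lines. Libraries of another cell line would bring another leading heavy chain V gene. The leading V gene of the wild type also led in the knockout label of each line, at 64.9% of V counts in the line with the lower share, which argues against this, although in SU-DHL-4 that gene is a pseudogene, and a group held only 783 to 1217 V counts. A response shared by both lines would switch the same genes, and 0% of the genes switched in TMD8 were switched the same way in SU-DHL-4. Many could not switch so there. SP140, TBC1D14 and SP110, switched on in TMD8, already stood at 21.59, 142.7 and 15.44 CPM in the SU-DHL-4 wild type. FOXC1 and CPXM1, switched off in TMD8, were at 0.01 and 0 CPM in it, so this share does not decide. For loss of chromosome stretches that hold several switched genes, 50% of the switched TMD8 genes had a gene switched the same way within 1 Mb. Some of these TMD8 neighbours overlap in position. AC005538.2 lies inside MSL3P1, ARHGEF35-AS1 overlaps ARHGEF34P and SP110 overlaps SP140. Their counts may not be separate, so the share does not decide and the explanation stays open in TMD8. In SU-DHL-4 0% had such a neighbour, which argues against it there. A loss that takes only 1 switched gene would leave no such neighbour, so these shares do not bear on it. Wild-type and knockout cultures that descend from different cells of a line may differ in this way, and the labels do not say how each culture was grown, so this stays untested.

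Lists that differed between the lines were the type I interferon response (adjusted p 5.77e-11), MHC class I presentation (4.01e-07), mitosis and G2/M (2.21e-09), cholesterol synthesis (1.76e-09), cytosolic ribosomal proteins (0.00157), NF-kB targets (0.00792) and mitochondrially encoded RNA (0.0107). With an estimated correlation the interferon list kept its call (0.00719) and the other 6 lost theirs (0.0751 to 0.898), so the p-values that follow rest on the preset correlation. By the labels as given, the first, the cholesterol list and the mitotic list moved in opposite directions in the lines.

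Exchanged TMD8 labels would turn that pattern of 3 lists. The TMD8 medians of −1.15, 0.40 and −0.25 would take the signs of SU-DHL-4 (0.51, −0.38 and 0.16). CFLAR RNA goes against the TMD8 label. With exchanged labels it would still stand at 0.74-fold, so it does not settle which labels are right. NF-kB targets would then have opposite signs (−0.55 and 0.13), and 9 lists would differ between the lines in place of 7. With an estimated correlation 0 would differ in place of 1, and 5196 genes would differ in place of 5277, so these counts do not settle which reading agrees better. A response shared across genes with turned labels would also give a negative correlation of the changes. The Pearson correlation was −0.01, so a response shared across genes was not seen under either labelling. Exchanged labels would only turn the sign of the correlation, so its value does not settle whether they were exchanged. Exchanged labels therefore stay open as an explanation. With 1 divergent library as the cause, a call would be lost without it, and the highest adjusted p over these 3 lists and the 12 libraries left out in turn was 9.48e-09. Without the genes on shifted chromosome stretches the highest was 1e-09. For GC content, gene length or level, 0% of 10000 random lists matched on these had a median difference as far from 0. These values argue against those 3 explanations as the whole cause. A dependence on the line, and a difference between the cultures unrelated to CFLAR, stay open beside exchanged labels.

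The difference between the lines was past the threshold for 5277 genes. Of the 200 splits of the libraries within the lines 100 were run, and only the real one gave as many. The highest other gave 5196, which is the split that exchanges the labels within 1 line and so keeps every library beside its replicates. Apart from the sign it is the same whichever line is exchanged. The splits that mixed wild-type and knockout libraries gave at most 3363, so a random mix of libraries did not give that many genes. Such splits cannot tell a response that differs between the lines from other differences between the cultures. For the 7 lists past the threshold chance cannot be excluded, since 35 of the 100 splits gave as many and the highest other gave 13. By list, the medians of the interferon, MHC class I, mitotic and cholesterol lists were farther from 0 than in every other split, while 8, 9 and 5 of 100 splits were as far from 0 for NF-kB targets, ribosomal proteins and mitochondrially encoded RNA. Within a line the 10 splits are too few for a share under 0.1. In TMD8, 1 of the 10 splits, the real one, gave 4213 genes and the highest other gave 5. In SU-DHL-4, 1 of 10 gave 5974 and the highest other 0, and between the wild-type lines 1 of 10 gave 13971 and the highest other 0. For lists, 10 of the 10 TMD8 splits gave at least the real 4, with 10 lists in the highest other, and 1 of the 10 SU-DHL-4 splits gave the real 9, with 7 in the highest other.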

How the results depend on the processing

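Leaving out the genes on shifted stretches was chosen after seeing the data, and the other alternatives before. No result reversed. Of the counts of genes, 333 values stayed within 1.5 times and 11 moved, and of the counts of lists 32 stayed and 9 moved. For named genes 6349 values kept their side of the threshold, 107 lost the call and 2 gained one. For single lists 253 kept it and 22 lost it, 18 of them with an estimated correlation. CFLAR ranged from 0.40 to 0.48 in TMD8 and from −1.17 to −1.03 in SU-DHL-4. In TMD8, genes at least 2-fold higher fell to 233 under the filter of 1 CPM in 3 libraries, which tests fewer genes. With the compared libraries only, 1285 genes rose and 1088 fell in TMD8 but 4351 rose and 4317 fell in SU-DHL-4. Such a fit has fewer libraries and also takes the spread from 1 line alone, where the main fit pools it over both lines. From the fits of the compared libraries only, 274 were lower in both lines and 336 were lower in TMD8 and higher in SU-DHL-4. Leaving out 1 library gave 1376 to 2487 genes higher and 1348 to 2507 lower in TMD8, 257 to 561 lower in both lines and 270 to 523 higher in TMD8 and lower in SU-DHL-4. The lowest of each came without TMD8 wild-type replicate 2, and 263 were lower in both lines without TMD8 wild-type replicate 3 or SU-DHL-4 wild-type replicate 2. TMD8 lists past the threshold ran from 4 to 8, with 8 without replicate 1 of the TMD8 libraries labelled knockout and 7 without their replicate 2. An estimated correlation left 1 list in TMD8, 0 in SU-DHL-4 and 1 in the difference, fry gave 10, 18 and 15, and DESeq2 size factors gave 7 in TMD8. The causes were not tested. The replicate block gave 4061, 5827 and 5153 genes for TMD8, SU-DHL-4 and the difference. At this depth the SU-DHL-4 knockout held 272 to 279 CFLAR counts per library, so depth limits genes well below that level.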

Other observations

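The scan chosen after the data were seen found further stretches whose genes shifted together. In SU-DHL-4, 59 genes at the tip of 6p had a median change of −0.874, 35 genes on 9q −1.005 and 260 genes on 15q −0.481, while 15 genes on 18p had 0.699 and 113 on Xq 0.242. In TMD8 these included 167 genes on 4q at 0.24, 320 on 7q at 0.225 and 52 on 19q at −0.341. Of the genes that rose in TMD8, 279 (13%) lay on any shifted stretch of the scan, and of those that fell 76 (3.7%).

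Immunoglobulin genes held 0.27% to 0.51% of the counts of a library. GZMB, a protease of cytotoxic lymphocytes, was at 197 ± 7.62 CPM in the TMD8 wild type and 159 ± 41.9 CPM under the knockout label (adjusted p = 0.304), and at 0 in SU-DHL-4. LCK, a kinase best known from T cells, was at 184 ± 4.26 CPM in the SU-DHL-4 wild type and fell in the knockout (−0.33, SE 0.05). Of the 24 genes switched in SU-DHL-4, 6 lay on chromosome X, and none of the 18 in TMD8.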
